A study of Mus musculus with 6 samples.

How the data were processed

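RNA sequencing was analysed for 6 libraries of the HT22 line with the inducible V5-tagged Klf13 transgene, 3 labelled Dox and 3 labelled vehicle, taken 8 hours after addition. Total RNA was extracted with TRIzol, per the labels' protocols, and libraries were made by a core facility. The submitters' processing notes name FastQC 0.11.3, HISAT2 2.1.0, StringTie 1.3.3 and DESeq2 with the build GRCm38, without a role or order for each. The annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here.

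The authors deposited a table of whole-number counts per gene symbol with 1 column per library, not normalized. It holds 29493 genes, none with a count of 0 in every library, and 0 rows that name no gene. They also deposited a table of the comparison of Dox with vehicle, which gives, per the file headers, a mean normalized signal, a log2 fold change with its standard error, a test statistic or score, a p-value and an adjusted p-value. In the deposited table the mean signal equals the mean of the counts divided by median-of-ratios size factors, the statistic equals the log2 fold change over its error, and every gene called has an adjusted p under 0.01. The p-value is missing for 107 genes and the adjusted p for 10368.

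Columns were assigned to samples by the names in the labels' descriptions. Genes with low counts were removed with filterByExpr, which left 18067. Libraries were scaled by TMM (factors 0.970 to 1.03), and levels are given as counts scaled to the effective library size (CPM). Dox was compared with vehicle by edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest, limma 3.58.1, R 4.3.3) on all 6 libraries without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change over the square root of the quasi-likelihood F. The common biological coefficient of variation was 12.0%. A fold change against a group with 0 counts in every library was set against a floor of 3 counts per library, which covers counting error only. With 3 libraries against 3, a permutation test of 1 gene cannot go below p = 0.1, so none was run.

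Gene lists were fixed before the data were examined, as were the tests and the other ways of analysis. There were 34 lists, of which 32 had the 5 or more tested members needed, and 849 of their 923 symbols were found in the table, 4 of them through an older symbol. Some genes were listed under both symbols and were counted once in each list. Other list members are not analysed here. Each was tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the lists. Klf13 was in no list. The rule for the genes named was also fixed: Klf13; the 8 largest rises, Klf13 included, and the 8 largest falls among genes past the test with non-overlapping groups, a mean of at least 2 CPM and a symbol that is not a predicted or clone-based name; up to 3 members with the smallest p of each called list and 1 of each other list with a member past the test; and Klf9 and Bcl2l1 whatever their p. It named 80 genes.

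The symbols were matched to GENCODE M21, which is on GRCm38, and 27367 of 29493 matched 1 gene, giving coordinates, length and GC content of the longest transcript (coding ones first), and genes sharing at least 50 exonic bases with another gene on either strand. That annotation may differ from the authors'.

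The fit was tested on simulated data: counts for the 18067 genes of the Dox against vehicle comparison were drawn from the real means, library sizes and dispersions. Of 50 genes changed by each fold, 6 were recovered at 1.25-fold, 28 at 1.5-fold, 39 at 2-fold and 45 at 4-fold, and 15 of 17801 unchanged genes were called. Both planted lists and 0 of 28 other lists were called, with genes drawn independently of each other. Most simulated genes were unchanged, while most genes tested in the real fit were called, so the shares recovered may differ there.

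Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 13.2 to 16.4), so no library was a repeat of another. The groups share replicate numbers, and the correlations of same-numbered libraries' deviations from their group means were 0.069, 0.052 and -0.094 over 14635 genes, so the numbers were not taken to pair the samples. Alternatives were DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at 5 CPM, a replicate block, an adjusted p of 0.01, glmTreat against a 1.2-fold change and leaving out each library. Offsets for transcript GC content and length, and a count of genes with no exonic overlap, were chosen after seeing the data, as were the counts at 2-fold under each alternative.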

Results

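Messenger RNA levels were measured by RNA sequencing in HT22, a neuronal cell line derived from the mouse hippocampus, carrying a stable transgene for V5-tagged KLF13. KLF13 is a zinc-finger transcription factor of the Krüppel-like family, and the transgene is placed under the tet repressor, so that doxycycline releases its expression. Cells received 1 µg/ml doxycycline (Dox, n = 3) or vehicle (n = 3) for 8 hours. The count table held 29493 genes, and total counts per library ranged from 38.6e6 to 52.9e6. The question, as the series title gives it, is how KLF13 acts in hippocampal neurons. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. No library had doxycycline in cells without the transgene, so changes due to KLF13 and changes due to the drug are measured together.

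Klf13, the induced gene, rose in every Dox library. Its level was 37.4 ± 1.55 CPM (counts scaled to the size of the library; mean ± SD, n = 3) with vehicle and 192.0 ± 11.1 CPM with Dox (SD, n = 3), a 5.13-fold rise (log2 fold change 2.36 ± 0.054 SE, edgeR quasi-likelihood test, adjusted p = 1.5e-06). The 3 vehicle libraries held 36.1 to 39.1 CPM and the 3 Dox libraries 183.6 to 204.6 CPM. Klf13 lies on the minus strand of chromosome 7, 63886351 to 63938915 (GRCm38, GENCODE M21), and shares no exonic sequence with another annotated gene. Its counts cannot separate the endogenous gene from transgene reads that match it.

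Large numbers of genes moved both ways, and most of the changes of at least 2-fold were falls. Of 18067 genes tested, 4687 rose and 5203 fell with Dox at an adjusted p under 0.05, together 54.7% of the genes tested. That share depended on the analysis: it was 45.1% with the DESeq2 Wald test, 43.0% at an adjusted p under 0.01, 33.4% with glmTreat against a fold change of 1.2, and 48.6 to 50.4% without 1 library. It was 31.6% with no filter on low counts, 59.2% with upper-quartile scaling and 71% with the stricter filter, mean CPM of at least 5. Among genes that changed at least 2-fold, 1357 fell and 314 rose, so that falls made up 81.2% of them, and at 4-fold or more 255 fell and 23 rose. The first principal component of the log CPM values held 58.8% of the variance and separated the 3 Dox from the 3 vehicle libraries. The balance of calls depended on scaling and on offsets. Upper-quartile scaling moved the median log2 fold change of the tested genes from 0.018 to 0.11. It gave 6246 genes higher and 4457 lower, and at 2-fold 443 higher and 1152 lower (72.2% lower). The GC offset, chosen after seeing the data, gave 5218 higher and 5036 lower, and 354 and 1254 at 2-fold (78% lower). The length offset, also chosen then, gave 4967 higher and 5010 lower, and 351 and 1260 at 2-fold (78.2% lower). With the stricter filter, mean CPM of at least 5, 92 genes were higher and 885 lower at 2-fold (90.6% lower).

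**Figure D1:**
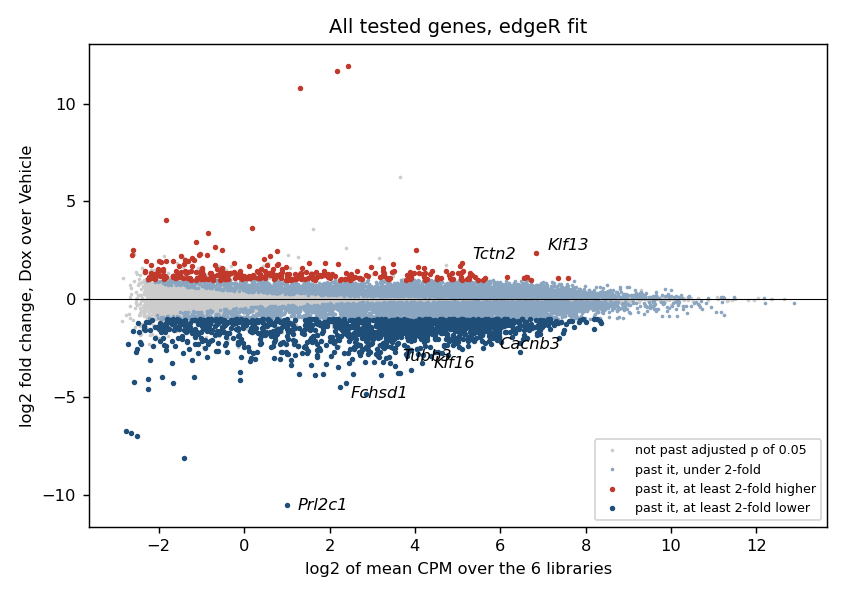
Log2 fold change (Dox over vehicle) of each of the 18067 tested genes against the log2 of its mean CPM over the 6 libraries, with genes past an adjusted p of 0.05 in blue and red. The 1357 genes that fell at least 2-fold lie over a wide range of levels, and Klf13 stands at 2.36.

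The largest falls, among genes of at least 2 CPM with separate groups and without predicted names, were in genes of several functions. Fchsd1, a membrane-binding F-BAR protein, fell 22.1-fold, from 9.02 ± 0.415 to 0.406 ± 0.0644 CPM (SD, n = 3 each). Xkr8, a phospholipid scramblase of apoptotic cells, fell 14.3-fold (log2 fold change -3.84 ± 0.25 SE) and Phf13, a chromatin reader, fell from 17.3 ± 1.34 to 1.203 ± 0.221 CPM (SD, n = 3 each). Log2 fold changes were -3.82 ± 0.15 for Sox12, a SOX transcription factor, -3.80 ± 0.28 for Cacnb1, a voltage-gated calcium channel beta subunit, -3.80 ± 0.16 for Pde10a, a cyclic nucleotide phosphodiesterase, and -3.76 ± 0.12 for Cand2, a regulator of cullin ligases (SE). Adjusted p ranged from 1.7e-06 for Fchsd1 to 5.5e-05 for Cacnb1. Prl2c1, a proliferin of the prolactin family, had 150 to 221 counts in the vehicle libraries and 0 in each Dox library, at least 56.9-fold lower against a floor of 3 counts per library. It belongs to a family of near-identical genes that can share reads, and its relatives Prl2c2, Prl2c3 and Prl2c5 fell by 0.27, 0.37 and 0.37 on the log2 scale. Fchsd1, Cacnb1 and Cand2 share exonic sequence with Rell2, Gm11629 and Rpl32, so part of their counts may belong to the neighbour.

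By the same limits, the rises after that of Klf13 were smaller than the largest falls. Genes outside these limits had larger rises in counts, such as the pseudogene Gm20657, named here after its values were seen. It had 0 counts in each vehicle library and 445 to 534 with Dox. How reads that match several genes were counted is not given, so its counts may hold reads of other genes. Tctn2, a protein of the ciliary transition zone, rose 3.65-fold from 14.7 ± 0.705 to 53.9 ± 1.04 CPM (SD, n = 3 each). Dgat2, which makes triglycerides, rose 3.24-fold (log2 fold change 1.70 ± 0.047 SE), Enpp3, an ectonucleotidase, rose 3.19-fold (1.67 ± 0.049) and Slc15a2, a peptide transporter, rose 3.10-fold (1.63 ± 0.13). Coq8a, needed for coenzyme Q synthesis, rose by 1.86 ± 0.17 and Ccdc39, an axonemal protein, by 1.62 ± 0.095, and both share exonic sequence with a neighbour (Cdc42bpa and Ttc14). Dleu2, a long noncoding RNA, had 4.75 to 5.25 CPM with vehicle and 5.68, 24.0 and 22.5 CPM in Dox replicates 1, 2 and 3, a log2 fold change of 1.79 ± 0.51 (adjusted p = 0.024). That call did not hold: the adjusted p was 0.068, 0.076 and 0.068 without vehicle replicate 1, 2 or 3, and 0.071 and 0.072 without Dox replicate 2 or 3, and 0.092 with limma-voom. Tctn2 lies at chromosome 5, 124598749 to 124627738, Dgat2 at chromosome 7, 99153658 to 99182719, Fchsd1 at chromosome 18, 37957431 to 37969774, Xkr8 at chromosome 4, 132724897 to 132732546, and Phf13 at chromosome 4, 151989633 to 151996258 (GRCm38).

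The 34 gene lists fixed before the data were examined were then compared with the other genes by camera, and 15 of the 32 with enough members were called at an adjusted p under 0.05, 5 higher and 10 lower. These calls used a preset inter-gene correlation of 0.01, and 0 of the 32 lists was called with an estimated correlation, where 4 had an unadjusted p under 0.05. Other splits of the same 6 libraries gave up to 11 called lists, though each has Dox and vehicle libraries on both sides. Counts of changed members are given beside the list calls. They were not tested against the 54.7% of all tested genes that were called.

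**Figure D2:**
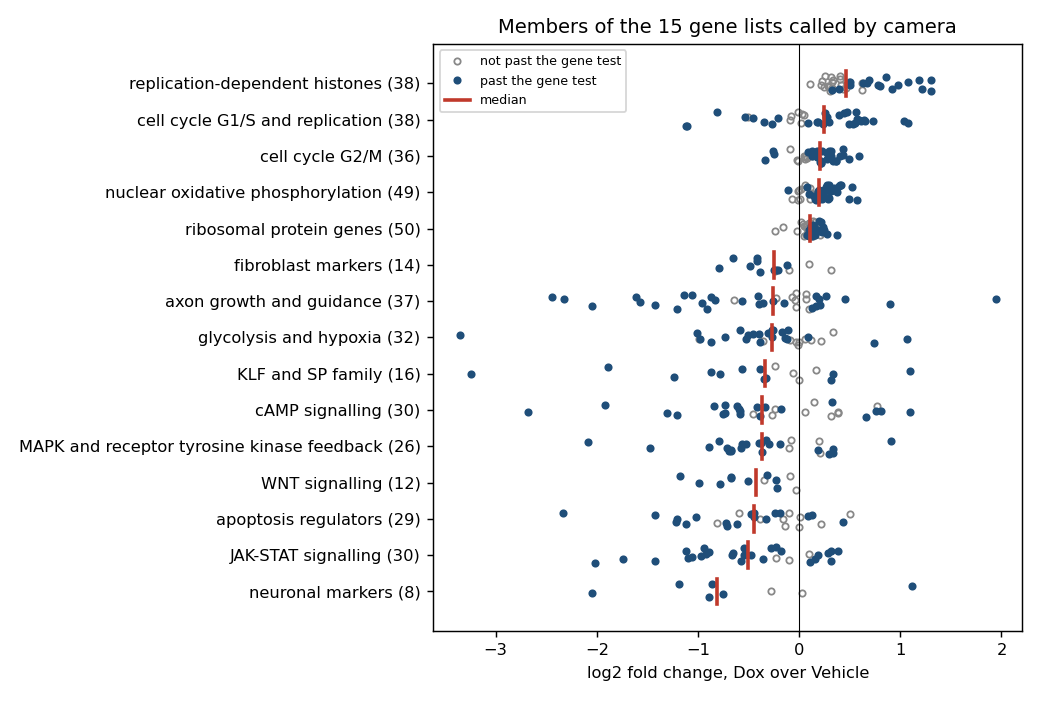
Log2 fold change (Dox over vehicle) of each tested member (points, filled where past the gene test) of the 15 lists called by camera, with each list's median as a bar and its number of tested members in brackets. The 5 lists called higher have medians from 0.111 to 0.465 and the 10 called lower from -0.809 to -0.246.

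Krüppel-like factor genes fell more often than they rose. In the gene list KLF and SP family, which leaves out Klf13, 9 of 16 tested genes fell, 3 rose and 4 did not pass, with the same counts adjusted over the list alone. Of 13 tested Klf genes without the SP genes, Klf13 among them, 7 fell and 4 rose. As a symbol family these were not called (camera at the preset correlation, adjusted p = 0.3). Klf16 fell 9.46-fold, from 32.6 ± 1.28 to 3.44 ± 0.141 CPM, Klf11 fell 3.71-fold, from 2.44 ± 0.145 to 0.655 ± 0.0622 CPM, and Klf10 fell from 49.5 ± 1.28 to 27.1 ± 0.808 CPM (SD, n = 3 each). Klf9, the close relative of Klf13, fell 2.37-fold, from 23.2 ± 1.44 to 9.83 ± 1.05 CPM (SD, n = 3 each, adjusted p = 5.6e-05). The list was called lower (median log2 fold change -0.337, adjusted p = 0.041), with adjusted p = 0.27 with an estimated correlation. The call, near its threshold, was lost without Vehicle replicate 2 (median -0.347, adjusted p = 0.056), without Dox replicate 2 (-0.337, 0.053), with the GC offset (-0.357, 0.061) and with the stricter filter, mean CPM of at least 5 (-0.351, 0.064), where the median was no smaller, and with the length offset (-0.224, 0.064), where it was.

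**Figure D3:**
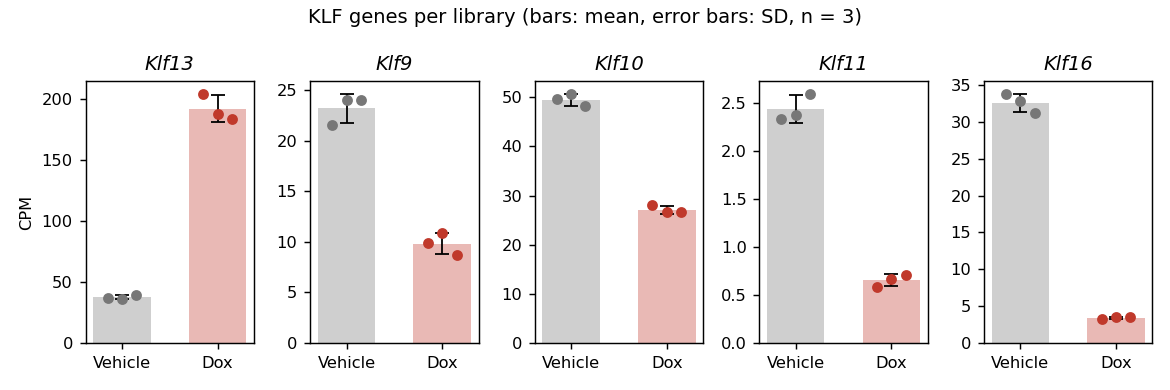
CPM of 5 KLF genes in each library (points), with the group mean (bars, each axis from 0) and SD (error bars, n = 3). Klf13 was higher in all 3 Dox libraries, and Klf9, Klf10, Klf11 and Klf16 were lower in all 3.

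Among the tested genes of neurons and of axon growth, falls outnumbered rises. Of 25 genes fixed in the gene list neuronal markers, 15 were in the table and only 8 were tested. Of these 8 tested genes 5 fell, 1 rose and 2 did not pass, the same adjusted over the list alone. Tubb3, neuronal beta-tubulin, fell 4.13-fold from 60.8 ± 0.21 to 14.7 ± 0.41 CPM (SD, n = 3 each), Dlg4, the postsynaptic scaffold PSD-95, fell by 1.19 ± 0.084 and Eno2, neuronal enolase, by 0.86 ± 0.062 on the log2 scale. The list median was -0.809 (camera adjusted p = 0.041), with adjusted p = 0.27 with an estimated correlation; the call was lost with the length offset (median -0.743, adjusted p = 0.059) and without any 1 of the libraries other than Dox replicate 2. In those fits the median stayed at -0.675 (without Vehicle replicate 3, adjusted p = 0.083) to -0.779 (without Vehicle replicate 1, 0.13), and the adjusted p was highest without Dox replicate 1 (median -0.757, 0.24), so the calls ended with little change in the median. The neuronal list was also not among those called with the stricter filter, mean CPM of at least 5, or with a replicate block. Of 37 axon growth and guidance genes, 19 fell, 9 rose and 9 did not pass (21 fell and 9 rose adjusted over the list alone). Semaphorin receptors were among them: Plxnd1 fell 5.45-fold and Plxnb2 2.21-fold. The median was -0.254 (adjusted p = 0.0069), with adjusted p = 0.43 with an estimated correlation, and the length correction ended the call (median -0.0734, adjusted p = 0.064).

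Components of cAMP signalling fell more often than they rose. Of 30 tested genes in the gene list cAMP signalling, 16 fell, 5 rose and 9 did not pass (16 fell and 6 rose adjusted over the list alone). Crtc1, a coactivator of CREB, fell 6.39-fold from 19.9 ± 1.15 to 3.12 ± 0.396 CPM (SD, n = 3 each), Prkaca, a catalytic subunit of protein kinase A, fell 2.47-fold, and Adcy6, an adenylyl cyclase, fell 2.32-fold. The list median was -0.365 (camera adjusted p = 0.018), with adjusted p = 0.35 with an estimated correlation. It was -0.206 with the length offset (adjusted p = 0.064) and -0.571 with the stricter filter, mean CPM of at least 5 (adjusted p = 6.6e-04). Of 29 genes in the gene list ion channels and calcium signalling, 12 fell, 1 rose and 16 did not pass (11 and 1 adjusted over the list alone), and Cacnb3, a calcium channel beta subunit, fell 4.71-fold from 82.7 ± 2.04 to 17.6 ± 0.153 CPM (SD, n = 3 each). The ion channel list was not called (median -0.144, adjusted p = 0.096), but was under the stricter filter, mean CPM of at least 5 (median -0.395, adjusted p = 0.0073).

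Among cytokine and growth factor signalling genes falls outnumbered rises. Of 30 JAK-STAT genes, 20 fell, 7 rose and 3 did not pass, the same adjusted over the list alone. The interferon receptor genes Ifnar1 and Ifngr2 fell 4.05-fold and 2.14-fold, and the kinase gene Jak1 fell 1.96-fold from 285.0 ± 4.43 to 145.7 ± 1.04 CPM (SD, n = 3 each). The list median was -0.508 (adjusted p = 0.0017), with adjusted p = 0.35 with an estimated correlation. Of 26 MAPK and receptor tyrosine kinase feedback genes, 17 fell, 5 rose and 4 did not pass (17 and 6 adjusted over the list alone); Etv4, an ETS factor, fell by 0.79 ± 0.036, Fgfr1, a fibroblast growth factor receptor, by 0.71 ± 0.039 and Erbb2, an EGF-receptor relative, by 0.69 ± 0.039 on the log2 scale. Its median was -0.371 (adjusted p = 0.014), with adjusted p = 0.43 with an estimated correlation and 0.059 after the length correction. Of 12 WNT genes, 9 fell and 3 did not pass, the same adjusted over the list alone. The WNT receptors Fzd7 and Fzd1 fell by 0.99 ± 0.041 and 0.68 ± 0.051, and Lef1, a transcription factor of the pathway, had a log2 fold change of -1.18 ± 0.11 (list median -0.429, adjusted p = 0.0074, with adjusted p = 0.27 with an estimated correlation).

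Among genes of cell death regulation falls outnumbered rises too. Of 29 tested apoptosis regulators, 15 fell, 3 rose and 11 did not pass (16 and 4 adjusted over the list alone). Bid, a pro-apoptotic BH3 gene, fell by 1.43 ± 0.068 and Tradd, a death-receptor adaptor, by 1.22 ± 0.060 on the log2 scale. Both genes promote cell death, and exonic overlap with Bcl2l13 may add to the counts of Bid. Bcl2l1, which encodes the anti-apoptotic Bcl-xL, did not pass (log2 fold change -0.60 ± 0.37, adjusted p = 0.22); its libraries ranged from 24.9 to 50.3 CPM with vehicle and from 19.5 to 40.2 CPM with Dox. The list median was -0.447 (adjusted p = 0.018), with adjusted p = 0.27 with an estimated correlation.

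More cell cycle genes rose than fell. Of 38 tested G1/S and replication genes, 23 rose, 8 fell and 7 did not pass, and of 36 G2/M genes 25 rose, 3 fell and 8 did not pass, each with the same counts of rises and falls adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, rose 2.12-fold from 122.9 ± 2.69 to 260.0 ± 4.69 CPM (SD, n = 3 each), and the replicative helicase genes Mcm3 and Mcm5 rose by 0.65 ± 0.020 and 0.62 ± 0.020 on the log2 scale. Among mitotic genes, Kif2c rose by 0.40 ± 0.024, Cdc20 by 0.36 ± 0.027 and Cdc25c by 0.60 ± 0.047. Medians were 0.246 for G1/S (adjusted p = 0.0053) and 0.209 for G2/M (adjusted p = 3.6e-04), both with adjusted p = 0.27 with an estimated correlation. Of 38 replication-dependent histone genes, 17 rose, 0 fell and 21 did not pass (13 rose adjusted over the list alone). Hist2h3c1 rose from 2.61 ± 0.0471 to 6.06 ± 0.151 CPM (SD, n = 3 each), Hist1h2bc by 1.304 ± 0.12 and Hist1h1c by 0.78 ± 0.053 on the log2 scale (list median 0.465, adjusted p = 1.8e-04, with adjusted p = 0.22 with an estimated correlation). The histone list was not among those called with the stricter filter, mean CPM of at least 5. It and the ribosomal protein list had been set beforehand as signs of RNA quality.

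Genes of energy metabolism were tested in separate lists. Of 49 nuclear-encoded oxidative phosphorylation genes, 35 rose, 1 fell and 13 did not pass (37 and 1 adjusted over the list alone). The complex I genes Ndufa8 and Ndufv2 rose by 0.52 ± 0.028 and 0.58 ± 0.042 and the complex III gene Uqcrfs1 by 0.30 ± 0.024 on the log2 scale (list median 0.198, adjusted p = 5.4e-06, with adjusted p = 0.47 with an estimated correlation), while of 15 mitochondrially encoded genes 1 rose, 3 fell and 11 did not pass (median -0.0144, adjusted p = 0.90). Of 32 glycolysis and hypoxia genes, 19 fell, 3 rose and 10 did not pass, the same adjusted over the list alone. Pfkfb4, which controls fructose 2,6-bisphosphate, fell 10.2-fold from 5.42 ± 0.386 to 0.528 ± 0.0186 CPM (SD, n = 3 each), and the glycolytic enzyme genes Pfkm and Hk1 fell by 0.98 ± 0.041 and 0.73 ± 0.026 (list median -0.265, adjusted p = 0.0024, with adjusted p = 0.25 with an estimated correlation). Of 50 ribosomal protein genes, 21 rose, 0 fell and 29 did not pass (14 rose adjusted over the list alone), with Rpl23 up by 0.37 ± 0.039, Rpl10a by 0.20 ± 0.022 and Rpl3 by 0.15 ± 0.026 (median 0.111, adjusted p = 5.2e-04, with adjusted p = 0.58 with an estimated correlation).

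Markers of other cell types showed a fall of fibroblast genes. Of 14 fibroblast markers, 10 fell, 0 rose and 4 did not pass (11 fell and 2 rose adjusted over the list alone). The collagen genes Col1a1, Col6a2 and Col6a1 fell by 0.66 ± 0.035, 0.79 ± 0.026 and 0.41 ± 0.024 on the log2 scale, Col1a1 from 2580 ± 76.0 to 1635 ± 58.9 CPM (SD, n = 3 each). The list was called lower (median -0.246, adjusted p = 0.0053), with adjusted p = 0.27 with an estimated correlation. Oligodendrocyte markers (3 of 5 fell, 0 rose, Pdgfra by 0.67 ± 0.040; adjusted p = 0.092) and astrocyte markers (1 of 5 rose and 1 fell, Sox9 by 0.51 ± 0.042; adjusted p = 0.77) were not called. For microglia and macrophage markers 1 of 4 tested genes rose and 1, Tmem119, fell by 0.61 ± 0.045, and of 3 endothelial markers Pecam1 rose by 1.27 ± 0.24. Counts in these 5 lists were the same adjusted over the list alone, except for fibroblasts. Mitochondrially encoded genes made up 3.67 to 3.86% of counts in every library, and among them mt-Nd3 rose by 0.36 ± 0.030. Nuclear-retained and small noncoding RNAs were not called (3 of 10 rose; Neat1 fell by 0.29 ± 0.025; adjusted p = 0.53).

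The other 12 tested lists, stress and hormone pathways among them, had members moving both ways and were not called. Of 39 ATF4 and amino acid response genes 13 rose and 14 fell (16 and 14 adjusted over the list alone; adjusted p = 0.38), and Chac1, a glutathione-degrading enzyme gene, doubled from 69.7 ± 0.288 to 140.8 ± 2.15 CPM (SD, n = 3 each). Of 26 unfolded protein response genes 11 rose, Atf6 by 0.59 ± 0.023, and 9 fell (11 and 10 adjusted over the list alone; adjusted p = 0.71). Among 19 clock genes 12 fell and 4 rose, Cry1 by 0.65 ± 0.033 (5 rose adjusted over the list alone; adjusted p = 0.11). Among 21 TGF-beta and BMP genes 10 rose and 8 fell, Smad3 by 1.79 ± 0.038 (11 and 8 adjusted over the list alone; adjusted p = 0.71), and the median of 0.132 and the mean of -0.0887 differ in sign. Of 23 p53 targets 8 rose and 11 fell, Sesn1 by 0.82 ± 0.042 (8 and 12 adjusted over the list alone; adjusted p = 0.52). In the remaining lists the counts were the same adjusted over the list alone. Of 25 interferon response genes 10 rose and 2 fell, Tap1 by 1.34 ± 0.088 (adjusted p = 0.23), and of 25 immediate early genes 8 rose, Ier2 by 0.75 ± 0.034, and 12 fell (adjusted p = 0.52). Of 24 cholesterol genes 9 rose and 7 fell, Srebf2 by 1.21 ± 0.028 (adjusted p = 0.52), of 20 NRF2 targets 3 rose and 9 fell, Me1 by 0.84 ± 0.032 (adjusted p = 0.52), and of 15 glucocorticoid receptor targets, Klf9 among them, 4 rose and 7 fell (adjusted p = 0.52). Of 16 heat shock genes 5 rose, Ahsa1 by 0.62 ± 0.027, and 5 fell (adjusted p = 0.44), and of 11 Notch genes 2 rose and 5 fell, Rbpj by 0.34 ± 0.034 (adjusted p = 0.38).

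The authors' deposited table of the same comparison called 7703 genes at its own threshold, an adjusted p under 0.01, of which 4288 were lower and 3415 higher. Klf13 had a log2 fold change of 2.34 ± 0.060 (SE) in the authors' deposited table. At an adjusted p under 0.05, 8701 genes were called in the same direction in both the authors' deposited table and the edgeR fit, 1189 in the edgeR fit alone and 183 of the tested genes in the deposited table alone. Across the 18067 tested genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the fit had a Pearson r of 0.957.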

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

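Klf13 kept its rise and its call under every alternative run, with log2 fold changes from 2.31 to 2.53. The counts of 4687 higher and 5203 lower genes stayed within 1.5 times under every alternative chosen beforehand except glmTreat against a 1.2-fold change, which called 2417 higher. Counting only genes with no exonic overlap, chosen after seeing the data, left 3116 higher and 3464 lower, and 208 higher and 878 lower at 2-fold, because fewer genes were tested. A filter at 5 CPM, with 11631 genes tested, cut the rises at 2-fold from 314 to 92 and the falls from 1357 to 885. The lower share went from 81.2% to 90.6%, so fewer tested genes alone do not account for the loss of rises. Without 1 library in turn, higher genes numbered 4146 to 4339 and lower genes 4841 to 4993, and at 2-fold 316 to 360 and 1318 to 1408. Large falls outnumbered large rises under each of these. The labels do not say whether the replicate numbers pair the samples. With a replicate block 4602 genes were higher and 5097 lower, and 14 lists were called, the neuronal list being lost. Leaving out 1 library gave 13 or 14 called lists, against 15, and an estimated correlation gave 0. The length offset left 10 lists, without the axon, cAMP, MAPK, KLF and neuronal lists. The GC offset called 15 lists, 14 of them shared with the main fit, so a list was gained where the KLF list was lost. With the stricter filter 13 lists were called, 12 of them shared, without the KLF, neuronal and histone lists. Of single values, the direction of the gene list mitochondrially encoded genes, not called, turned with the stricter filter, mean CPM of at least 5 (median 0.00501), without Vehicle replicate 2 (0.00383) and in the test, though not the median, without Dox replicate 1 (-0.00767). Its median grew to -0.0409 without Vehicle replicate 1. The gene list immediate early genes turned in the test with the GC offset (median -0.0138). The median of the gene list nuclear-retained and small noncoding RNA, not called, went from 0.133 to -0.113 without Dox replicate 2. The gene Neat1 turned with the length offset (0.0708). The cause of these turns was not tested. The 8701 genes called with the same direction as in the authors' deposited table changed by less than 1.5 times with a refit in DESeq2 or an adjusted p of 0.01. In simulation, at these library sizes and dispersions with 3 libraries a group, 28 of 50 genes changed 1.5-fold were recovered. There 17801 of 18067 genes were unchanged, while the real fit called 54.7%. The share recovered may therefore differ in the data.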

Other observations

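Genes of the primary cilium were examined after Tctn2 and Ccdc39 were found among the largest rises. Tmem231, a partner of Tctn2 in the ciliary transition zone, rose by 1.45 ± 0.052 on the log2 scale, and a list of cilium genes was then drawn up from general knowledge without Tctn2, Tmem231 and Ccdc39. Of its 50 tested members 30 rose, 11 fell and 9 did not pass. Tctn3 rose by 1.35 ± 0.037, Ift80 and Ift74, of the intraflagellar transport machinery, by 1.13 ± 0.053 and 0.78 ± 0.035, and Tmem67 by 0.52 ± 0.053, while Arl13b, a ciliary membrane GTPase, fell by 0.75 ± 0.072. The list median was 0.32 (camera p = 2.4e-04 with the preset correlation, and p = 0.027 with an estimated one), at percentile 100 of 10000 random lists matched on transcript length and expression. These tests were chosen after Tctn2 and Tmem231 had been seen, so a coordinated rise of cilium genes with Dox is a hypothesis.

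Gene families grouped by the stem of their symbols showed further sets, all chosen by size (at least 10 tested members) and not by function. Of 149 families 36 were called by camera at the preset correlation, 23 higher and 13 lower, none of those named here with an estimated one (adjusted p of 0.42 or more). All 10 tested Exosc genes, subunits of the RNA exosome, were called higher (Exosc2 by 0.68 ± 0.055), but Exosc6 (41.9, 3.95 and 37.2 CPM in the Dox libraries and 3.00 to 6.95 CPM with vehicle) did not separate the groups. Of the mitochondrial ribosome's genes, 36 of 51 Mrpl genes rose and 4 fell, and 19 of 31 Mrps genes rose and 1 fell (Mrpl18 rose by 0.50 ± 0.023). Of 20 Pcdhb genes, clustered protocadherins similar enough to share reads, 15 rose and 1 fell. The families named here are examples, and those given as lower are not the most strongly called. Among the families called lower, 8 of 11 Sept genes, septins, fell and 1 rose, and 7 of 11 Sema genes, semaphorins, fell and 1 rose.

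The excess of large falls over large rises was weighed against technical causes; the offsets were run after the excess had been seen. The ratio of falls to rises of at least 2-fold was 4.32 before any offset. After removal of each library's trend with transcript GC content it was 3.54 (95% exact binomial interval 3.15 to 4). With transcript length it was 3.59 (3.19 to 4.05). These ratios argue against either trend alone as the whole cause. The intervals take genes as independent, which they are not, and the offsets were not applied together. Scaling stays open: a shift of all log2 fold changes by 0.29 would balance falls and rises, more than the scalings tried gave, but an overall change in RNA per cell is not measured here. An effect of doxycycline itself also stays open, since no library had the drug without the transgene; the gene list ATF4 and amino acid response, which stress on mitochondrial translation may raise, had a median of 0.056 (0.0322 without Vehicle replicate 2 and 0.148 with the GC offset), between the bounds that would decide. A repressor role of KLF13 is a candidate explanation that these libraries do not separate from the drug.

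A possible sign of direct action was sought within the transcripts, without a positive result. In the first 200 bases of the transcript, a CACCC box on either strand, the kind of site that KLF proteins bind, was present in 543 of 1130 protein-coding genes that fell at least 2-fold (48.1%) and in 517 of 1130 genes not called and matched on GC content there (45.8%), an odds ratio of 1.10 (95% interval 0.926 to 1.3, Fisher's exact test, p = 0.29). The promoter itself was not searched, and so short a site is common among matched genes too, so direct action stays open. Over genes of all types, the 5′ ends of genes that fell at least 2-fold were richer in GC (median 66.5%) than those of genes not called (56.0%). These sets also differed in level (median 17.0 against 3.19 CPM with vehicle), which was not matched.

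Some counts jumped between replicates. Of 11878 genes with a group mean of at least 5 CPM, 79 differed at least 4-fold between replicates of 1 group, and 6 of these were called, Dleu2 and Exosc6 among them. Exonic overlap with another gene was found in 56.8% of the 74 that could be placed and in 32.0% of the other genes (odds ratio 2.79, 95% interval 1.72 to 4.58, Fisher's exact test, p = 1.4e-05), which read assignment between overlapping gene models would give. Whether reads moved stays open: in a test chosen after the jumps were seen, the partner's counts offset the jump best in the observed order of replicates, of 6 orders, in 8 of 32 genes with separate partners (25%, 95% interval 11.5 to 43.4%, 16.7% by chance). The largest share of jumps in 1 library was 23.5% (15.5 to 33.1%), Dox replicate 2. This argues against a single aberrant library as the source of most jumps. That interval and the Fisher test take genes as independent. Some jumping genes share exons with each other, so the interval and the p-value may be too narrow and too small. No biological explanation was tested.

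The rise of 3 lists of short transcripts was set against lists matched on transcript length and expression. The median of the oxidative phosphorylation list lay at percentile 99.99 of 10000 such random lists and that of the histones at 100. Matched genes were drawn independently of each other for every list, and GC content was not matched. The estimated inter-gene correlation was 0.49 for oxidative phosphorylation, so its percentile cannot exclude length and level. It was -0.011 for the histones, an estimate from only 6 libraries. Their percentile argues against length and level alone only as far as the members vary independently. The ribosomal protein list, at percentile 97.58 (97.28 to 97.88 with the error of the draws), cannot be told apart from its matched lists at the bound set before the draw, and may reflect transcript length and expression alone. Among the fallen lists, the medians of axon genes (percentile 5.42), KLF and SP genes (6.13), WNT genes (5.99), fibroblast markers (5.06) and MAPK genes (3.89) lay inside the middle 95% of their matched lists, and those of JAK-STAT (0.25), apoptosis (0.28), glycolysis (0.67), neuronal (0.85) and cAMP genes (1.41) below it.

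The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4687 and 5203 genes higher and lower, and 314 and 1357 at 2-fold, and was the only 1 of the 10 with as many. The highest of the other 9 gave 3 genes in a direction. Each of those 9 has Dox and vehicle libraries on both sides, so the difference between the groups becomes spread within a side. Few calls were bound to follow, and these counts cannot decide whether chance gave the real split's numbers. For the lists the real split gave 15 calls, and the highest other, Vehicle 1, Vehicle 2 and Dox 2 against the rest, gave 11.

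Values apart from these comparisons: 8 genes had 0 counts in every library of 1 group and at least 10 in each library of the other, and 5 of the 7 found in the annotation are annotated pseudogenes, such as Gm20657 with 445 to 534 counts in the Dox libraries. In 145 genes with no exonic overlap the fall was at least 4-fold; if synthesis had stopped at the addition of doxycycline and decay were first order, such a fall within 8 hours needs a half-life of at most 4 hours, and an 8-fold fall, seen in 18 of them, at most 2.7 hours. Genes that rose at least 2-fold had a median vehicle level of 0.822 CPM, against 17.0 CPM for those that fell as much.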
